A study of Mus musculus with 2 samples.

How the data were processed

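H3K9me3 chromatin immunoprecipitation and sequencing was carried out on hindbrain from embryonic day 15.5 mice of strain B6NCrl, with fragments of 300 to 500 bp per the labels. The 2 samples are biological replicates, pools of 78 and 62 embryos of both sexes, and they form the only group. The deposited files are 4 lists of narrow peaks on mm10, one per replicate, a list called on the pooled alignments of both replicates, and a replicated list derived from these lists, per the deposited file descriptions. Each list was made from alignments together with control alignments. The controls themselves were not analysed here. The aligner, the peak caller, its thresholds and the rule for the replicated list are not given in the sources used here.

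Column 7 of each deposited peak list gives the signal of a peak, read here as a linear ratio (fold enrichment) over control, since all values lie above 1 and are not whole numbers. Columns 8 and 9 of the deposited lists give −log10 p and −log10 q, the p-value and q-value of the authors' caller. These values belong to a peak within its list and were used to describe, rank or filter peaks of that list. The replicated list carries the values of the pooled peaks. Read depth per sample is unknown, so no interval that needs depth is given, and peak numbers of the replicates cannot be compared as amounts of H3K9me3.

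Peaks were placed on the reference genome GRCm38.p6, whose chromosome lengths equal those of mm10, with GENCODE vM21 gene models. All genomic comparisons used chromosomes 1 to 19, X and Y, and peaks on scaffolds were left out of them. Gene tests covered 21919 genes, 21911 of them protein-coding and 8 listed noncoding genes. Replicated peaks touched the body of 1662 of these genes (7.58%) and the promoter, within 1 kb of any annotated TSS, of 404 (1.84%). The principal TSS is that of the protein-coding transcript with the best APPRIS rank, then the longest.

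The replicates were compared by overlap of at least 1 bp, against 1000 random placements of the other replicate's peaks within their chromosomes (bedtools 2.31.1). Signals were compared over overlapping pairs. Peak midpoints were assigned to promoter, exon, intron or intergenic sequence, in that order, against 1000 random placements. For 18 gene lists, the number of members with a peak was compared with 10000 random lists drawn from other genes within 20 bins of gene length. Random lists ignore that members of a family lie side by side, so 1000 rotations of the peaks along each chromosome were run as an alternative. The lists were Zfp genes, clustered protocadherins, olfactory receptors, vomeronasal receptors, Hox genes, clustered histones, ribosomal proteins, imprinted genes, germline genes, hindbrain transcription factors, neuronal genes, progenitor and glial genes, housekeeping genes, liver genes, muscle and heart genes, blood and immune genes, vascular and meningeal genes, and the H3K9 methylation machinery. Position within Zfp genes was tested by sign-flip permutation over genes with 100000 draws. All tests are two-sided, and adjusted p-values are Benjamini-Hochberg over lists or classes. With 1 group of 2 samples, no test between samples was possible. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

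The genes named follow a rule set, like the lists, tests and all but the last alternatives below, before the data were examined. For each list that passed, up to 4 members with the largest covered share of the gene body were named, and up to 2 marked members of other lists. To these came the 20 protein-coding genes of at least 2 kb with the largest covered share, the 10 genes nearest to the peaks of highest signal, the 10 widest blocks of peaks less than 5 kb apart, and the 10 windows of 500 kb with most covered bases. Genes outside this rule are marked as named after their values were seen.

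The list test was tested on simulated data with randomly placed peaks over the 21919 genes. Of 200 lists of 40 genes in which 20 genes were given a peak, 100% passed at an unadjusted p below 0.05, and of 200 lists without added peaks 1.5% passed. These lists were drawn at random and their peaks were scattered, so the rate does not cover clustered peaks or families of neighbouring genes. In simulated peak lists that shared 20% of 10000 peaks, the overlap test recovered 19.9% above random placement. Alternatives covered each replicate's peaks alone, the pooled peaks, a q of 0.01 or less, other overlap rules, a promoter window of 2.5 kb, a minimum of 10% of the gene body, lists not matched on length, rotated peaks, and placement outside assembly gaps. The last alternatives were added after seeing the data. These left out peaks with −log10 q of 50 or more, kept replicated peaks that overlap a peak of each replicate, kept 1 member per run of overlapping gene bodies, used the principal TSS alone, set the position within Zfp genes against rotated peaks with genes selected in the same way, and selected Zfp genes by a peak in the body or the promoter window.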

Results

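Trimethylation of histone H3 at lysine 9 (H3K9me3), a modification known from transcriptionally silent chromatin, was mapped by chromatin immunoprecipitation and sequencing in hindbrain of mouse embryos at embryonic day 15.5. The hindbrain holds the developing cerebellum, pons and medulla. The labels give 1 group of 2 biological replicates, a pool of 78 embryos of both sexes (replicate 1) and a pool of 62 (replicate 2), and no second condition. The comparisons are therefore between the replicates, and between marked sites and randomly placed sites or randomly drawn genes. Replicate 1 held 67078 peaks with a median width of 215 bp, which covered 17.5 Mb of chromosomes 1 to 19, X and Y. Replicate 2 held 32173 peaks with a median width of 237 bp, which covered 9.08 Mb. The authors' replicated list held 14759 peaks with a median width of 436 bp, which covered 7.73 Mb, or 0.284% of these chromosomes. Read depth per sample is unknown, because the peak lists carry no read totals.

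The 500 kb window with the most covered bases was on chromosome 18, from 37300001 to 37800000 in mm10, where replicated peaks covered 40.3% of the sequence (38.0% with replicate 1 peaks, 28.8% with replicate 2 peaks). This window holds beta and gamma protocadherin genes, which encode neuronal cell adhesion molecules. The neighbouring window from 36800001 to 37300000, over the alpha protocadherins, ranked sixth by this measure at 20.3%. On chromosome 7, the window from 17650001 to 18150000 with 5 Ceacam genes, which encode carcinoembryonic antigen-related adhesion molecules, reached 29.2%. Its share was 31.1% with replicate 1 peaks and 17.8% with replicate 2 peaks. Secretoglobin genes of the Scgb family at 33450001 to 33950000 on the same chromosome stood in a window covered to 22.9% (26.7% with replicate 1 peaks, 15.2% with replicate 2 peaks). A window of cathepsin genes on chromosome 13 (61150001 to 61650000) reached 22.2%, and a window on chromosome 12 (114150001 to 114650000) with 41 immunoglobulin heavy-chain variable segments reached 21.8%. With replicate 1 and replicate 2 peaks, the cathepsin window was covered to 25.5% and 14.8%, and the immunoglobulin window to 25.8% and 14.3%. The vomeronasal receptor genes from Vmn1r66 to Vmn1r71 on chromosome 7 (10250001 to 10750000) lay in a window covered to 19.6% (25.5% with replicate 1 peaks, 13.6% with replicate 2 peaks). Of the remaining windows among the 10 with most covered bases, the one at 147350001 to 147850000 on chromosome 4 holds 7 Zfp genes and was covered to 16.7%. The window with Zfp873 and Zfp938 on chromosome 10 (82000001 to 82500000) was covered to 18.3%, and the window at 121550001 to 122050000 on chromosome 4, with 1 protein-coding gene, to 17.4%. Joining replicated peaks less than 5 kb apart gave 7265 blocks, of which 421 spanned at least 10 kb. The widest block lay over gamma protocadherin genes at 37655993 to 37777951 on chromosome 18. It spanned 122 kb, and peaks covered 75.3% of it.

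The clustered protocadherins were the gene list with the highest share of marked members. A replicated peak lay in the gene body of 52 of 56 of these genes, against 8.08 ± 2.40 (SD over 10000 draws) in random lists of genes of the same length. Alpha and gamma genes overlap in their bodies, so a peak can mark several of them. With 1 member per run of overlapping bodies, 23 of 23 were marked (22.4-fold, a setting chosen after seeing the data). The permutation test over all 56 gave an adjusted p of 0.00072, the smallest these draws can give after Benjamini-Hochberg adjustment when 5 of 18 lists reach the limit. At the promoters, within 1 kb of an annotated transcription start site (TSS), 48 of 56 were marked, against 0.743 ± 0.852 (SD) in random lists (adjusted p = 0.00072, permutation test). All 56 genes lie side by side on chromosome 18, while random lists are drawn from all chromosomes. The genes are therefore not independent, and these p-values and folds treat them as if they were. With rotated peaks, which keep neighbouring genes together, the counts of bodies and promoters also passed (adjusted p below 0.05 for each, permutation test). By subfamily, 10 of 13 alpha, 20 of 22 beta and 18 of 21 gamma promoters carried a replicated peak. Replicate 1 peaks marked 53 gene bodies and 51 promoters, and replicate 2 peaks marked 52 and 49. Among individual genes, Pcdhb4 (chromosome 18, 37307455 to 37311172) was covered over 73.4% of its length and Pcdhb22 over 73.4%, while Pcdhb13 reached 70.5% and Pcdhb19 68.7%. The fold over random lists depended on the peak list. It was 6.44 for gene bodies with replicated peaks, 2.39 with replicate 1 peaks alone and 3.17 with replicate 2 peaks alone. For promoters it was 64.6, 19 and 36.9. The covered share of Pcdhb4 was 53.5% with replicate 1 peaks and 38.8% with replicate 2 peaks.

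**Figure D1:**
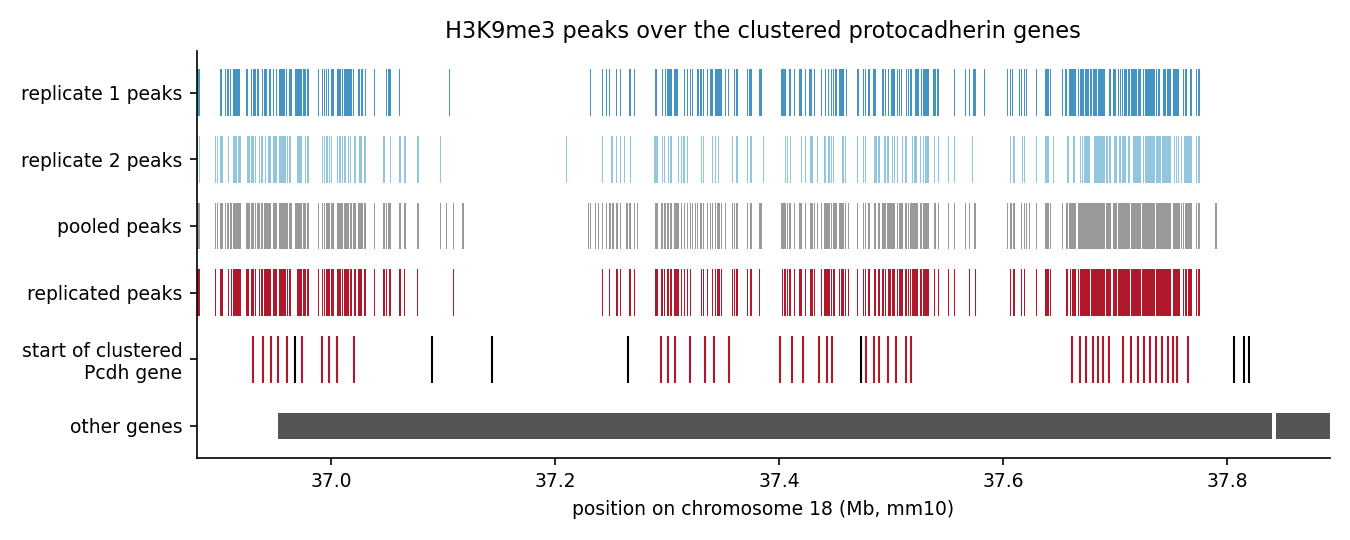
Peaks over the clustered protocadherin genes on chromosome 18 (mm10, position in Mb on the horizontal axis). Rows show the peaks of each replicate, the pooled peaks and the replicated peaks, then the outermost start of each clustered Pcdh gene (red where a promoter of the gene carries a replicated peak, black where none does) and the bodies of other genes; 48 of 56 starts are red.

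Zinc finger genes of the Zfp series, many of which encode DNA-binding repressors with a KRAB domain, had the most marked gene bodies of the lists with replicated peaks, though not with replicate 1 peaks, where olfactory receptors had more (217 against 184). A replicated peak lay in the body of 128 of 391 Zfp genes, against 20.1 ± 4.11 (SD) in length-matched random lists, a 6.35-fold excess (adjusted p = 0.00072, permutation test). With replicate 1 peaks alone, 184 genes were marked (2.81-fold), and with replicate 2 peaks alone 156 (3.64-fold). When peaks were rotated along their chromosomes, which keeps their clustering, the excess was 3.6-fold (adjusted p = 0.00899, permutation test, the smallest that 1000 rotations can give when 4 of 18 lists reach the limit). Chromosome 7 held 28 of these marked genes among its 92 Zfp genes, chromosome 17 held 18 of 45, chromosome 13 held 17 of 36 and chromosome 4 held 13 of 30. The most covered members were Zfp873 on chromosome 10 (82048123 to 82064745, 86.0% of the gene), Zfp110 on chromosome 7 (12834761 to 12850577, 84.2%), Zfp2 on chromosome 11 (56.7%) and Zfp606 on chromosome 7 (56.0%).

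Within the marked Zfp genes, the last exon was covered far more than the promoter. In the 128 genes with a replicated peak, 45.3% of the last exon was covered on average (SD 33.9), against 0.942% of the window within 1 kb of the principal TSS (SD 4.91). The mean difference was 44.3 percentage points, with a standard error of 3.05. The last exon was covered more than the promoter in 106 genes, the promoter more than the last exon in 3, and both were covered equally in 19. The last exon had any covered base in 107 genes. Of the last 1 kb of the gene, 36.4% was covered on average, with any covered base in 75 genes. A two-sided sign-flip permutation test over genes gave p = 1e-05, the smallest that 100000 draws can give. Neighbouring genes are not independent, so this p describes these genes. With rotated peaks and genes selected in the same way, a comparison chosen after seeing the data, the difference was 0.391 ± 2.87 points (SD) and at most 10.3 in 1000 rotations (p = 0.002, permutation test, the smallest they can give). The last exons of Zfp873 (100% covered), Zfp2 (92.9%), Zfp606 (88.8%) and Zfp110 (86.7%) were almost fully marked, with no covered base at their principal promoters. The difference was 28.2 points with replicate 1 peaks alone and 28.8 points with replicate 2 peaks alone. Counted over any annotated TSS, 34 Zfp genes had a marked promoter, 5.96-fold over random lists (adjusted p = 0.00072, permutation test). At the principal TSS alone, 6 Zfp genes were marked, and that count did not pass (1.56-fold, adjusted p = 0.993, permutation test, a setting chosen after seeing the data). With replicate 1 or replicate 2 peaks alone the excess at any TSS was 2.84-fold or 3.22-fold, and with rotated peaks 2.96-fold (adjusted p = 0.0450, permutation test).

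**Figure D2:**
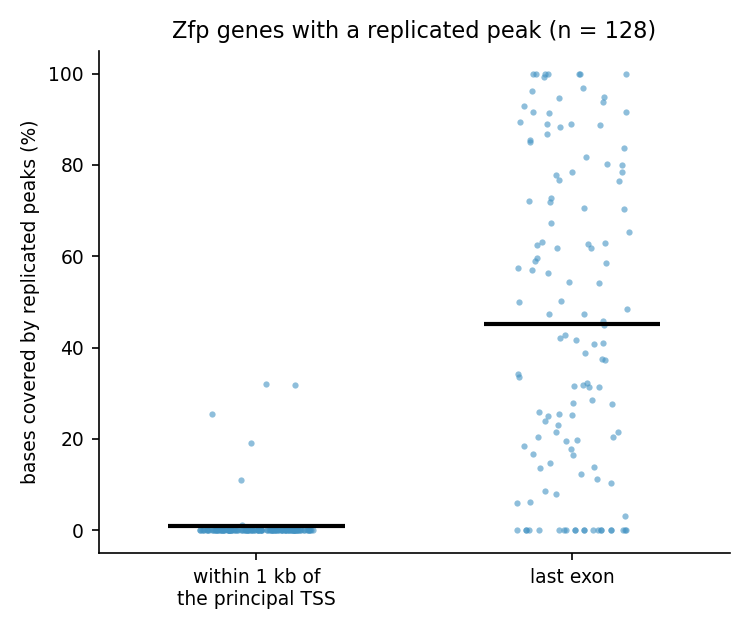
Percent of bases covered by replicated peaks (vertical axis) within 1 kb of the principal TSS and in the last exon, for the 128 Zfp genes with a replicated peak. Each point is a gene and the bars are the means, 0.942% and 45.3%.

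Imprinted genes, which are expressed from the copy of a particular parent, were also marked. A replicated peak lay in the body of 21 of 41 listed genes, against 3.38 ± 1.63 (SD) in random lists, and in the promoter of 14, against 0.682 ± 0.821 (SD). Both counts passed (6.22-fold and 20.5-fold, adjusted p = 0.00072 for each, permutation test). Some listed genes overlap or adjoin, so a peak can mark several of them, and the counts are not of separate loci. The peak at 6729189 to 6730804 on chromosome 7, for example, lay at the starts of both Peg3 and Usp29 (named after their values were seen). The promoters included those of Peg3, Mest, Nnat, Airn, Impact and Zrsr1, which were named after their values were seen. The largest covered shares were those of Nap1l5 on chromosome 6 (58905233 to 58907076, 34.4%), the noncoding Peg13 on chromosome 15 (22.8%), Blcap on chromosome 2 (11.4%) and Ndn on chromosome 7 (11.2%). Replicate 1 peaks marked 28 gene bodies (2.77-fold over random lists) and replicate 2 peaks marked 25 (3.58-fold). At promoters the excess was 11.3-fold with replicate 1 peaks alone and 8.44-fold with rotated peaks (adjusted p = 0.0180, permutation test, the smallest possible when 2 lists reach the limit). The covered share of Nap1l5 was 49.9% with replicate 1 peaks and 11.1% with replicate 2 peaks. In the same order, the shares were 17.2% and 33.2% for Peg13, 5.71% and 10.5% for Blcap, and 9.47% and 18.5% for Ndn.

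Of the chemoreceptor genes of the nose, the vomeronasal list passed with random lists and with rotated peaks, and the olfactory list with length-matched random lists but not with rotated peaks. The difference between the families was not tested. Among vomeronasal receptor genes, 80 of 326 had a replicated peak in the gene body, against 11.8 ± 3.32 (SD) in random lists, and 40 had a marked promoter, against 5.50 ± 2.28 (SD) (adjusted p = 0.00072 for each, permutation test). Marked bodies were found in 40 of 206 Vmn1r and 40 of 120 Vmn2r genes, and the most covered was Vmn1r70 on chromosome 7 (10631532 to 10636530, 43.0%). The vomeronasal excess in bodies was 6.76-fold, and 3.83-fold or 4.62-fold with replicate 1 or replicate 2 peaks alone, which marked 84 and 53 promoters. With rotated peaks it was 3.45-fold in bodies (adjusted p = 0.00899, permutation test) and 3.99-fold in promoters (adjusted p = 0.0240, permutation test). Among olfactory receptor genes, 65 of 1092 had a marked body (5.95%, below the 7.58% of all genes), against 28.8 ± 4.88 (SD) in random lists of equally short genes (adjusted p = 0.00072, permutation test), and 52 had a marked promoter, against 19.9 ± 4.07 (SD, adjusted p = 0.00072). Replicate 1 peaks marked 217 olfactory bodies (3.15-fold) and replicate 2 peaks 116 (2.55-fold), and they marked 165 and 89 olfactory promoters. With at least 10% of the body covered, 21 olfactory genes were counted, and the count did not pass (1.20-fold, adjusted p = 1, permutation test). Neither olfactory count passed with rotated peaks (adjusted p = 0.557 for bodies and 0.676 for promoters, permutation test). Against lists not matched on length, the olfactory bodies stood below random, at 0.776-fold (adjusted p = 0.0751, permutation test). The most covered were Olfr345 (48.6%), Olfr356 (33.1%) and Olfr348 (29.0%) on chromosome 2, and Olfr399 on chromosome 11 (30.2%). Replicate 1 peaks alone covered 46.8% of Olfr345, 30.9% of Olfr356, 21.6% of Olfr348 and 28.9% of Olfr399. Replicate 2 peaks alone covered 25.4% of Olfr345, no base of Olfr356, 12.4% of Olfr348 and 15.0% of Olfr399.

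None of the lists of hindbrain cell types and of basic cell functions passed. Of 33 hindbrain transcription factors, 1 had a marked body (Foxp2, 0.185% covered), against 3.21 ± 1.5 (SD) in random lists (adjusted p = 0.658, permutation test). Replicate 1 peaks marked 7 of these factors and replicate 2 peaks 5, against 7.98 and 5.96 in random lists. Of 20 neuronal genes, 3 were marked, against 2.99 in random lists (9 and 5 with replicate 1 and replicate 2 peaks), Nefm (2.93% covered), Syt1 (0.217%) and, named after its values were seen, Rbfox3 (0.0858%). The progenitor and glial list had 1 marked member of 19, Pax3 (0.514%, with no base covered by replicate 1 peaks), against 1.03 in random lists. Replicate 1 and replicate 2 peaks marked 0 and 3 members of that list. No gene body was marked among 39 Hox genes, 67 clustered histone genes, 76 ribosomal protein genes, 20 housekeeping genes and 18 blood and immune genes with replicated peaks. Replicate 1 and replicate 2 peaks marked 3 and 1 Hox genes, 1 and 0 ribosomal protein genes, 0 and 1 housekeeping genes, 2 and 2 blood and immune genes, and no histone gene. For the replicated list, a count of 0 allows shares of up to 7.69%, 4.48%, 3.95%, 15% and 16.7% of these lists by counting error alone, and random lists held 1.27, 1.37, 2.00, 0.802 and 1.01 marked genes. A count of 0 is the lowest possible, and it gave unadjusted p-values from 0.256 to 0.887 (permutation test). Against length-matched lists, depletion of these lists could therefore not have been detected. The lists of other tissues did not pass either, with 1 marked liver gene against 0.747 in random lists, 2 muscle and heart genes against 1.18, and 2 vascular and meningeal genes against 0.994. With replicate 1 and replicate 2 peaks these counts were 4 and 4 for liver, 4 and 1 for muscle and heart, and 5 and 4 for vascular and meningeal genes, and none passed. The marked members were Cyp3a11 among 16 liver genes (20.2% covered, promoter included), Ttn (5.68%) and Ryr1 (0.205%, with no base covered by replicate 2 peaks) among 16 muscle and heart genes, and Pdgfrb (0.904%) and Tek (0.603%) among 14 vascular and meningeal genes. Among 39 germline genes, Ddx4 (1.26%) and Tex11 (0.123%) were marked, the former with no base covered by replicate 2 peaks, and among 24 genes of the H3K9 methylation machinery 1 was marked, Morc2a (0.506%). Random lists held 2.90 and 2.04 marked genes. Replicate 1 and replicate 2 peaks marked 12 and 6 germline genes and 7 and 3 machinery genes. Adjusted permutation p-values of these lists were between 0.658 and 1.

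**Figure D3:**
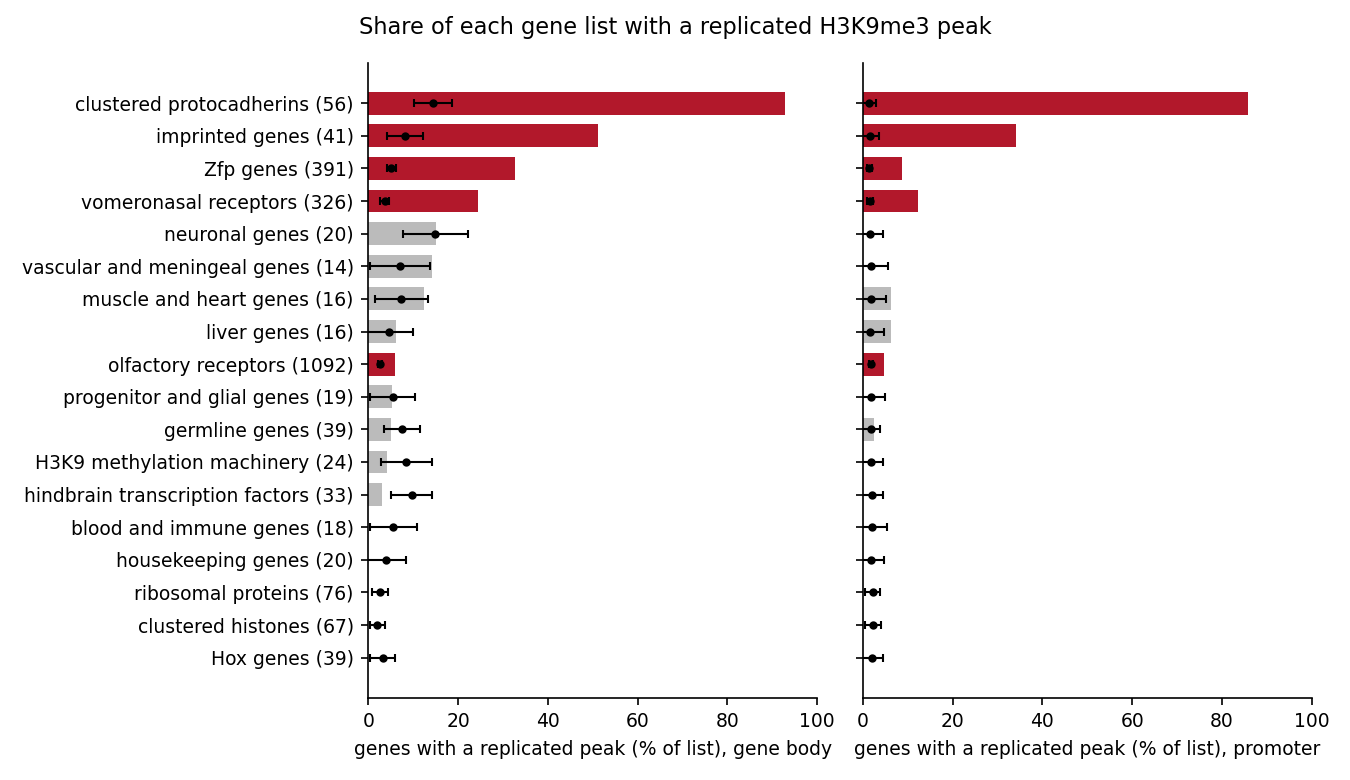
Share of each gene list with a replicated peak in the gene body (left) or within 1 kb of a TSS (right), in percent, with the number of members in parentheses. Red bars are lists whose adjusted permutation p was below 0.05, grey bars are other lists, and black points with error bars are the mean and SD of 10000 random lists; clustered protocadherins lead both panels, with 52 and 48 of 56 genes.

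Outside the fixed lists, several genes were almost wholly covered by replicated peaks, some of them less so with the peaks of a replicate alone. Gm21738 on chromosome 14 (19415857 to 19418930) was covered over its full length by a peak of modest signal, a 2.41-fold ratio over control. That peak had a −log10 q of 58.8, and 58.1% of its bases matched the same peak at a shift of 351 bp, as in a tandem repeat. Klf14, an intronless Krüppel-like transcription factor gene on chromosome 6 (30956023 to 30959078), was covered over 97.6% of its length, and over 96.0% with replicate 2 peaks alone. Its peak at 30956097 to 30959181 had the highest signal of the replicated list, a 13.0-fold ratio. Scgb2b24 on chromosome 7 was covered over 96.9%, but over 75.7% with replicate 1 peaks and 57.9% with replicate 2 peaks. Ugt1a1 on chromosome 1 (88211959 to 88218997), which encodes the enzyme that conjugates bilirubin, was covered over 94.8%, and the nearby Mroh2a (88226986 to 88262289) over 81.6%. With replicate 1 and replicate 2 peaks, Ugt1a1 was covered over 90.7% and 91.5%, and Mroh2a over 73.5% and 68.9%. The sperm motility kinase genes Smok2b and Smok2a on chromosome 17 reached 83.7% and 67.3%, AU022751 on chromosome X 73.4% (20.5% and 44.9% with replicate 1 and replicate 2 peaks) and Ceacam14 on chromosome 7 64.8%. The replicate 1 and replicate 2 shares were 66.7% and 68.1% for Smok2b, 70.1% and 44.8% for Smok2a, and 41.4% and 50.4% for Ceacam14. Of the 20 protein-coding genes of at least 2 kb with the largest covered share, 9 were beta protocadherins. Several peaks with the next highest signals lay in or near Zfp genes, with ratios of 10.5 at Zfp981, 8.65 at Zfp978 and 8.34 at 60120 bp from the TSS of Zfp990 (all on chromosome 4), and 8.22 at Zfp810 on chromosome 9. A peak on chromosome Y (259000 to 259459, ratio 11.4) and a peak on chromosome 16 (3243372 to 3243946, ratio 9.61) lay 537950 and 347096 bp from the nearest TSS among the genes tested, those of Zfy1 and Olfr161. The peak on chromosome Y matched itself in 64.5% of bases at a shift of 20 bp.

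Coverage differed between chromosomes. Chromosome 7 held 10.6 kb of replicated peaks per Mb, 3.42 times the autosomal value of 3.09 kb per Mb, followed by chromosome 17 (7.47 kb per Mb), chromosome 4 (5.53) and chromosome 18 (4.64). The ratio of chromosome 7 to autosomes was 2.64 in replicate 1 and 2.56 in replicate 2. Chromosome Y held the least, 0.0587 kb per Mb (0.0812 with replicate 1 peaks and 0.0621 with replicate 2 peaks). Whether peaks on X and Y could be called as readily as on autosomes was not tested, so their low coverage need not mean less H3K9me3. Chromosome X held 0.611 kb per Mb, 0.198 times the autosomal value. Here the replicates differed, with ratios of 0.715 in replicate 1 and 0.416 in replicate 2, and no test was made between these 2 values.

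**Figure D4:**
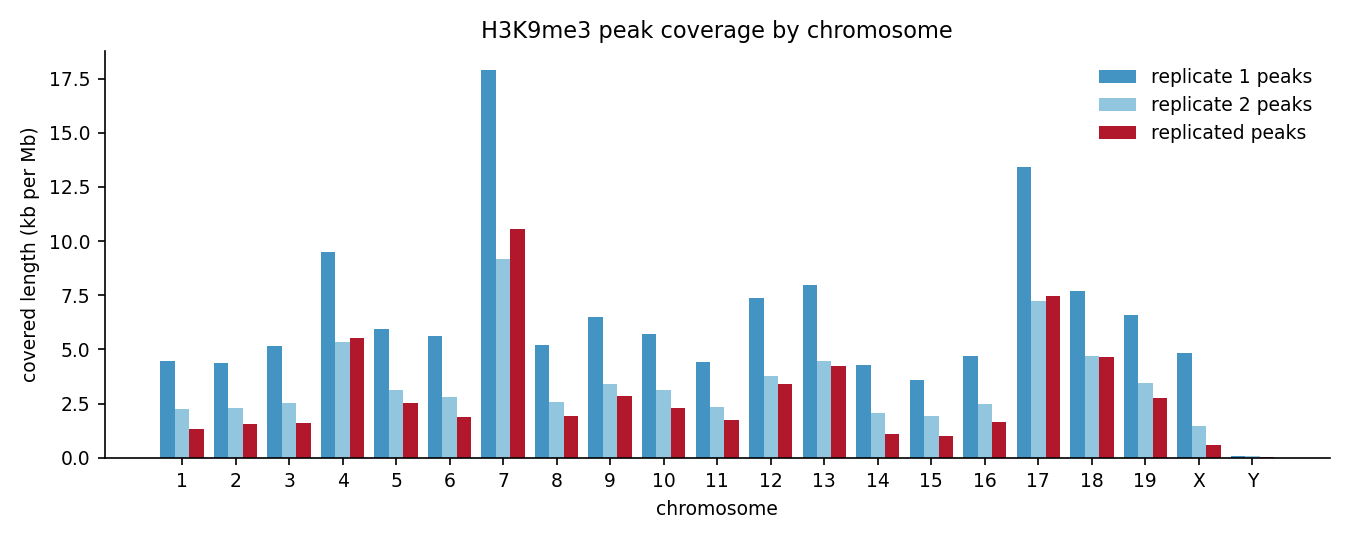
Length covered by peaks (kb per Mb, vertical axis) for chromosomes 1 to 19, X and Y, in replicate 1, replicate 2 and the replicated list. Chromosome 7 stands highest in all 3 lists, and chromosomes X and Y are lowest in the replicated list (0.611 and 0.0587 kb per Mb).

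By annotation, replicated peaks lay more often in exons and between genes, and less often in introns, than randomly placed intervals. Of the 14506 replicated peaks on these chromosomes, 58.5% had their midpoint between genes (random 51.0 ± 0.416, SD over 1000 placements), 27.8% in introns (random 38.9 ± 0.399) and 5.61% in exons (random 3.47 ± 0.151). Promoters held 8.07% (random 6.63 ± 0.209). Each class differed from random placement (adjusted p = 0.002, permutation test, the smallest that 1000 placements can give). This placement scatters peaks singly, whereas the replicated peaks lie in clusters, so the SDs and p-values in this paragraph are probably too small. For the overlap of replicate 1 peaks, rotation gave an SD of 0.173 percentage points, against 0.034 with placement. No rotation was run for location or sequence composition. With replicate 1 peaks alone the exon share was 3.58% (1.08-fold of random), with replicate 2 peaks 4.43% (1.32-fold) and with pooled peaks 3.74% (1.10-fold). The promoter excess was not found with each replicate's own peaks, which stood at 0.918-fold of random in replicate 1 (adjusted p = 0.002, permutation test) and 0.996-fold in replicate 2 (adjusted p = 0.859). The GC content of replicated peaks was 42.7%, against 42.2 ± 0.0612% in random intervals. The ratio of observed to expected CpG dinucleotides was 0.159, against 0.193 ± 0.00163 (p = 0.002 for each, permutation test). The share of soft-masked (repeat) bases was 33.4%, against 34 ± 0.285% (p = 0.034, permutation test). It stood above random with replicate 1 peaks, at 36.6% against 34.3% (p = 0.002, permutation test), and was 34.4% against 34.1% with replicate 2 peaks (p = 0.152). Random intervals were not limited to sequence to which reads can be mapped. These shares therefore do not show whether repeats carry the mark more or less often than other sequence.

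The replicates shared many more peaks than chance, yet most peaks of either list had no counterpart. Of the replicate 1 peaks, 18.6% overlapped a replicate 2 peak by at least 1 bp, against 0.812 ± 0.034% (SD) with randomly placed peaks. Of the replicate 2 peaks, 38.2% overlapped a replicate 1 peak, against 1.69 ± 0.076% (p = 0.002 for each, permutation test with 1000 placements). With the same number of strongest peaks from each replicate, the shares were 26.0% and 26.7%. With only peaks of q of 0.01 or less in both lists, they were 16.6% and 32.3%. With all peaks and a reciprocal overlap of at least 50%, they were 8.67% and 18.1%. Across 11405 overlapping pairs, the log2 signals correlated with Pearson r = 0.23 and Spearman rho = 0.18. Among 1637 pairs with q of 0.01 or less in both replicates, rho was 0.33. These correlations are across peaks, which are not independent replicates. Of the 14759 replicated peaks, 88.8% had a q of 0.01 or less, against 48.7% of all pooled peaks, whose q-values they carry. In the lists called on 1 replicate the shares were 16.5% (replicate 1) and 17.9% (replicate 2). Those q-values come from other calls, so these shares are not a like comparison. Each replicated peak is a pooled peak, and 78.0% of them overlapped a peak of both replicates by at least 50% of either peak. On the assembled chromosomes, 15.5% of replicated peaks overlapped a peak of replicate 1 alone, 5.73% of replicate 2 alone and 0.345% of neither.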

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

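All tests of explanations in this part were chosen after the result was seen. Unplaced and unlocalized scaffolds entered no comparison, and 253 of the replicated peaks (1.71%) lay on 20 of them. The most marked scaffold alone held 64 of these peaks. No expected number was computed for them. These peaks covered 231 kb, with a median signal of 3.86 over control, against 3.63 on chromosomes, and a median −log10 q of 12.5, against 3.22.

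Chromosome X held 3.69 times as many peaks in replicate 1 as in replicate 2, while the autosomes ranged from 1.81 to 2.29. A few loci on X are argued against, since the 3 bins of 5 Mb with the largest excess held 20.0% of it. Depth or a calling threshold stays open: the X ratio fell from 4.27 among peaks with q above 0.1 to 3.36 and then to 2.37 among peaks with q of 0.01 or less, where its 95% exact binomial interval (1.90 to 2.98) included the highest autosome ratio of 2.20. Among the few X peaks with q of 0.001 or less (70 and 32), the ratio was 2.19, within the autosome range of 1.39 to 2.26. Another candidate explanation is a different share of X in the ChIP and the control material of a replicate, since both pools mix male and female embryos, and 93.9% of 33 bins along X had a ratio above that of every autosome. That spread is also what a threshold or a difference in X chromatin between the pools, which was not tested, would give.

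As a set, peaks with the smallest q did not have the highest signal. The 24 replicated peaks with −log10 q of 50 or more had a median signal of 3.47, below the 75th percentile of the other peaks (4.06), which argues against exceptional enrichment over control for the set. A peak on chromosome Y (11.4) and a peak on chromosome X at 170009024 (5.63) are exceptions, above the 95th percentile of the others (4.92). Tandem repeats may account for part of the 24 peaks, since 8 of the 24 (33.3%) matched themselves in at least 50% of bases at a shift of 20 to 1000 bp, against at most 20.8% in 1000 draws of peaks of like width (mean 4.61%). Some of the 24 peaks adjoin, while the draws treat them as separate. The peaks with the largest −log10 q, 134 and 133, matched themselves in only 27.7% and 30.7% of bases. Both lay in Sfi1 on chromosome 11, named after its values were seen. No biological explanation was tested.

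Most peaks of either replicate had no overlapping peak in the other. Weak calls that do not recur may account for part of this: 11.4% of replicate 1 peaks with q above 0.1 overlapped a replicate 2 peak, against 58.0% of those with q of 0.001 or less. With only peaks of q of 0.01 or less in both lists, which also drops weak counterparts of strong peaks, the shares were 16.6% and 32.3%, not above those of all peaks (18.6% and 38.2%), so how much weak calls account for stays open. Domains broken into narrow peaks at different places may add to it, since 40.5% of the replicate 1 peaks without overlap lay within 5 kb of a replicate 2 peak, against 8.76 ± 0.702% (SD) with rotated peaks and at most 14.2%. No biological explanation was tested.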

How the results depend on the processing

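Alternatives with peaks of very small q left out, peaks overlapping both replicates, 1 member per run of gene bodies or the principal TSS were chosen after seeing the data. The comparison of Zfp positions with rotated peaks, and with genes selected by body or promoter window, was added then too, and the latter selected the same number of genes, 128. Of 459 alternative values, 432 were counted as unchanged. Tested values counted so if they kept their direction and side of the threshold. A list that passed in neither setting also counted as unchanged, whatever its direction. Peak numbers and numbers of passing lists counted within a fixed fold change, and other values within an interval or the spread between replicates. For lists that passed, 95 of 100 values were unchanged, and for the other lists 257 of 260. Beside these, 55 of 92 covered shares of named genes moved by more than the spread between replicates when taken from a replicate alone. Except where stated, the cause of a change was not tested. Olfactory receptor bodies did not pass with 10% of the body covered (1.20-fold) or rotated peaks (1.79-fold), and stood below random at 0.776-fold with lists not matched on length. Olfactory promoters did not pass with rotated peaks (1.93-fold), nor Zfp promoters at the principal TSS (1.56-fold). With unmatched lists, histone and ribosomal protein bodies fell below random (0 marked genes, adjusted p = 0.0246 and 0.0202, permutation test), and with pooled peaks germline promoters passed (3.89-fold). Promoter location stood below random with pooled peaks (0.969-fold) and at 0.918 to 0.996-fold with single replicates. The difference in soft-masked share turned to 1.51 percentage points above random with pooled peaks and 0.297 to 2.21 with single replicates. Signal concordance rose to rho 0.332 with q of 0.01 or less, 0.240 for −log10 p and 0.216 with reciprocal overlap. The share of replicated peaks that met the overlap rule was 78.7% with 1 bp and 43.0% with 50% of the pooled peak. The X to autosome ratio was 0.416 to 0.715 with single replicates, and that of chromosome 7 was 2.56 to 2.64, or 2.88 with pooled peaks. With q of 0.01 or less, 11042 replicate 1, 5774 replicate 2 and 28156 pooled peaks remained. Read depth is unknown, so what deeper sequencing would add cannot be told. No paired analysis was possible because the labels give 1 group.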

Other observations

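The test and the peaks below were chosen after their values were seen. Several gene families outside the fixed lists had replicated peaks in many members. Marked gene bodies were found in 7 of 11 Klra genes on chromosome 6, which encode natural killer cell receptors, 9 of 11 Skint genes on chromosome 4, 9 of 17 Nlrp genes and 7 of 15 Ceacam genes on chromosome 7, 8 of 34 Scgb genes on chromosome 7, 9 of 21 Sult genes, which encode sulfotransferases, 9 of 22 Ugt genes on chromosome 1 and 17 of 100 Cyp genes. These were the 8 of 246 families of at least 10 genes that passed against length-matched random lists (adjusted p = 0.00615 for each, permutation test, the smallest possible for 8 of 246 families), with folds from 3.30 for Cyp to 13.3 for Klra. The hypothesis that other multi-copy families carry replicated peaks more often than random genes was then tested with 10000 rotations of the peaks, which keep neighbouring genes together. Of the families, 0% passed both tests, and the lowest adjusted rotation p was 0.711 (permutation test). Unadjusted rotation p-values were 0.0052 for Nlrp, 0.0118 for Klra, 0.024 for Skint and 0.0256 for Ceacam (permutation test). For Scgb, Sult, Cyp and Ugt they were 0.0306, 0.035, 0.0866 and 0.087. With adjustment over 246 families, a family passing alone needed a count that no rotation reached (adjusted p 0.0492). A failure here therefore does not show that clustering accounts for the excess of a family. Except for Sult and Cyp, the marked members of each of these 8 families lay on 1 chromosome, and neighbouring genes are not independent. Overlap of gene bodies within these families was not checked, and where bodies overlap a peak can mark several members. The counts are therefore not of separate loci. The marked Sult genes lay on chromosomes 7 and 17, and the marked Cyp genes on chromosomes 1, 4, 5, 7, 15, 17 and 19.

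At imprinted loci, replicated peaks also lay away from gene starts. A peak on chromosome 9 (89879369 to 89879798) lay 30.1 kb upstream of the Rasgrf1 TSS, and a peak on chromosome 12 (109528717 to 109529055) lay 11.9 kb upstream of Meg3. The peak nearest to H19 was 154 kb away.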
